A study of Homo sapiens with 2 samples.

How the data were processed

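Small RNA libraries were made from A375 cells, a human melanoma line. Per the labels' protocols, 1000000 cells were seeded in 10 cm dishes, treated with DMSO after 24 h and harvested 48 h later, RNA was extracted with the miRNeasy Mini kit, and libraries followed standard Illumina protocols. Per the submitters' processing notes, CASAVA 1.8 and cutadapt 1.2.1 (adapter trimming) were used. The aligner, miRNA annotation release, genome build and treatment of reads with several matches are not given in the sources used here. Trimming and length selection set which short reads enter a library, and ligation of adapters favours some sequences, so RPM of different miRNAs are not exact molar ratios.

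The deposited values are RPM, 1 per hairpin and mature miRNA and library, with decimal commas. The authors' columns each sum to 1000000 over all rows, so RPM here means reads per 1000000 read assignments. A read assigned to several rows counts in each of them. The deposited table held 1546 rows, 1095 hairpins and 1497 mature names. No deposited row was 0 in both libraries, so a miRNA without a row got no value. Every value above 0 was a whole multiple of the smallest in its column (100% of values within 0.01 reads), so read assignments were recovered, 10816826 and 15428446 in total. The authors' totals appear to count many reads once for each hairpin: 45 mature names had several hairpins, and of the 34 with a mean of 10 RPM or more, 27 had a lowest copy at 0.9 of the highest or more. In the other 7, including miR-92a-3p, some reads may belong to 1 copy only, and the highest copy can then understate the miRNA. Intervals and tests on reads cover counting error only, since reads from PCR are not independent molecules.

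Both columns were matched to their samples by the sample descriptions, and 0 other columns of values were present. Both samples form 1 group. The labels call the replicates independent and say nothing more of their origin, so the spread between them may be partly technical. Replicates are not paired with anything, and no comparison between groups was possible.

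The design fixed before the data were examined called for the sum of copies with unequal values. Because the values of most copies were nearly equal, as if the same reads were assigned to each, the highest copy per mature name was used instead, a departure chosen after the table was seen, and the summed version was computed as an alternative. The reduced total was 77.6% and 78.3% of the deposited total, and shares are percentages of it. The names miR-199a-3p and miR-199b-3p belong to identical sequences and both stayed in the total.

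A miRNA counted as expressed at 10 RPM or more in both libraries. Logarithms used a pseudocount of 1 RPM, so log2 differences of low miRNAs are understated. Fisher's exact test, two-sided, compared the reads of each miRNA with all other read assignments of each library, for miRNAs with at least 10 reads in sum. Benjamini-Hochberg adjustment covered 869 tests, with a limit of 0.05 and a fold above 2 after adding 0.5 reads to each count. In simulated libraries with 200 of 863 miRNAs changed by 3-fold, 200 were recovered and 4 of 663 unchanged ones were called. The simulated reads varied by counting error only, and all changed miRNAs had a mean of 10 RPM or more. The simulation thus checks the computation and gives no error rate for low miRNAs or for the wider spread between these libraries. Arms were compared for hairpins with a summed mean of 100 RPM or more. The median level of each list with at least 3 members in the table was placed among 10000 random lists of the same size. Names without a row were left out of these medians, which can make them too high. Intervals were 95% bootstrap intervals.

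The lists and the rule for named miRNAs were fixed before the data were examined. They were 19 family lists (18 by seed and the miR-23/24/27 group), 7 clusters, a melanocyte and melanoma list, 7 lists of other cell types and a list of entries overlapping tRNA, snRNA or snoRNA, 35 in all. The named miRNAs were the 20 highest, the top 2 of each list and the whole melanocyte and melanoma list, up to 10 with a mean of 100 RPM or more that passed the library test, the 3 most balanced and 3 most one-sided hairpins at 1000 RPM or more, and the extremes of each cluster. Others, such as miR-99a-5p, miR-199a-5p, miR-122-5p, miR-451a and miR-4454, mir-192 and the passenger arms were chosen after their values were seen.

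Of the 1095 hairpins, 1094 were matched by name to GENCODE 29 (GRCh38), used for positions, host genes and hairpin GC content. The build behind the deposited values may differ. A planned search for seed sites in the BRAF 3' UTR was not run, because mature miRNA sequences were not used here.

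Alternatives were other RPM minima, pseudocounts of 0.1 and 10, scaling by the median ratio of expressed miRNAs, removal of the most abundant miRNA, other fold limits, no read minimum and leaving out each replicate. Summed copies, shares of the deposited total, arm ratios without a pseudocount, family lists without the miR-23/24/27 group, other neighbour distances and subsets of neighbours, copies or arms were added after the data were seen.

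Bounds for the tests of explanations were written before the tests, apart from those on miR-199 and on sequencing depth at 10 RPM or more. The way a bound was applied was revised after the values were seen. An explanation is now set aside where the interval excludes the bound written for it as a cause, and left open where the interval includes the bound. This moved the tests of hairpin level and hairpin GC content from open to set aside and the shared shift of neighbours from set aside to open. In the test of genomic copies, a pair with the same neighbour for both copies and a pair counted from both sides were removed, and an exact p of 0.05 was required, which moved it from met to open. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.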

Results

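Small RNA sequencing measured microRNAs (miRNAs), the short RNAs that guide repression of messenger RNAs, in A375 cells, an established human melanoma cell line. The series concerns miRNAs that regulate the BRAF-X1 transcript, and the part analysed here profiled cells treated with DMSO, the solvent used as vehicle, for 48 h. It holds 1 group of 2 libraries, called independent replicates in the labels, so no condition was compared and no p-value speaks of a treatment. The libraries held 10816826 (replicate 1) and 15428446 (replicate 2) read assignments. These were recovered from the deposited RPM (reads per 1000000 read assignments), where 1 read equalled 0.0924 and 0.0648 RPM. The table listed 1497 mature miRNAs from 1095 hairpins. Names are given without the species prefix hsa- that the file carries. Values below are mean RPM ± SD over the 2 libraries (n = 2) unless replicate values are given.

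The first question was which miRNAs make up the small RNA pool of these cells. MiR-100-5p had the highest mean at 74782 ± 18188 RPM, followed by miR-21-5p, a miRNA raised in many cancers, at 53854 ± 8314 RPM, miR-191-5p at 53448 ± 11946 RPM, miR-92a-3p at 52790 ± 972 RPM and miR-27b-3p at 50503 ± 2374 RPM. Next came let-7a-5p at 41893 ± 717 RPM, miR-22-3p at 38295 ± 4652 RPM, miR-181a-5p at 28068 ± 5443 RPM, miR-10a-5p at 23536 ± 1699 RPM and miR-10b-5p at 20818 ± 1303 RPM. These 10 held 56.2% ± 1.19 (SD, n = 2) of the RPM after copies of one mature name were reduced to 1 value. MiR-30a-5p (20811 ± 5258 RPM), miR-92b-3p (18178 ± 1159 RPM), miR-30d-5p (17351 ± 2858 RPM), let-7f-5p (13317 ± 2025 RPM) and miR-16-5p (12532 ± 2735 RPM) followed. The list of 20 ended with miR-26a-5p (12190 ± 1434 RPM), miR-99b-5p (12168 ± 3176 RPM), miR-21-3p (11868 ± 806 RPM), miR-140-3p (10956 ± 91.7 RPM) and miR-27a-3p (9952 ± 861 RPM). The range of mean ± SD of miR-100-5p overlapped those of miR-21-5p and miR-191-5p, and these overlapped those of miR-92a-3p and miR-27b-3p. The order of the first 5 was thus not fully resolved. Within each library miR-100-5p was still the highest. In replicate 1 it had 61921 RPM against 59733 for miR-21-5p, and in replicate 2 87643.5 against 61895.5 for miR-191-5p. MiR-21-5p and miR-191-5p changed order between the libraries. Several leading miRNAs have more than 1 genomic copy with reads assigned to each: with copies summed, let-7a-5p stood first at 125579 RPM, miR-92a-3p second at 97242 RPM, miR-100-5p was number 3 in rank and miR-181a-5p number 4 at 56135 RPM. Summing also raised let-7f-5p to 26436 RPM, miR-16-5p to 25062 RPM and miR-26a-5p to 24374 RPM. Most copies had nearly equal values, as if the same reads were assigned to each. The sums thus appear to count many reads more than once, and do not show that let-7a-5p was the most abundant.

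**Figure D1:**
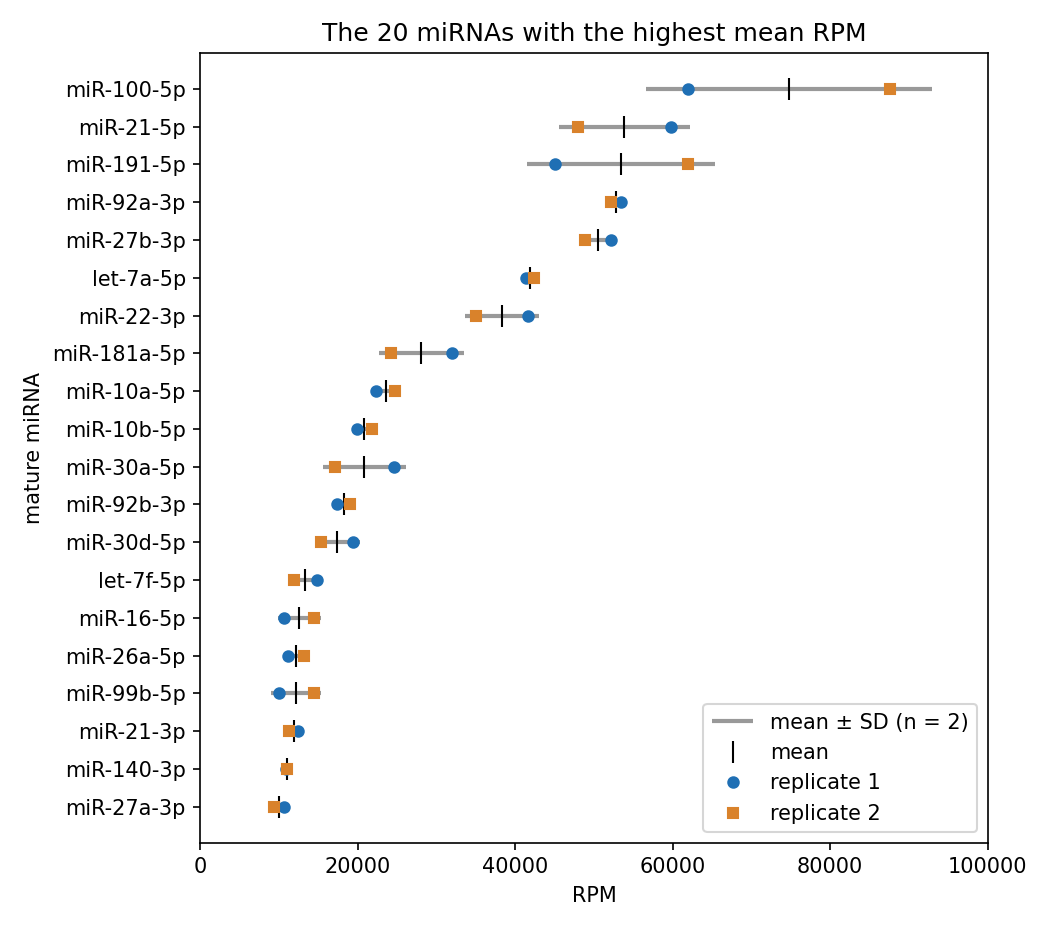
RPM of the 20 miRNAs with the highest mean in A375 cells treated with DMSO, on a linear axis from 0. Circles are replicate 1, squares replicate 2, ticks the mean and grey lines the mean ± SD (n = 2); miR-100-5p, at 61921 and 87643 RPM, shows the widest gap of the 20 in RPM.

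In GRCh38 with the GENCODE 29 annotation, the hairpin of miR-100-5p (MIR100) lies on chromosome 11 from 122152229 to 122152308 on the minus strand, in an intron of the long noncoding gene MIR100HG. One of the 3 let-7a hairpins, MIRLET7A2, lies in an intron of the same gene from 122146522 to 122146593. MIR21, which gives both miR-21-5p and miR-21-3p, lies on chromosome 17 from 59841266 to 59841337 on the plus strand and overlaps an exon of VMP1. MIR191 lies in an intron of DALRD3 on chromosome 3 from 49020618 to 49020709, and MIR27B in an intron of C9orf3 on chromosome 9 from 95085445 to 95085541. The hairpins of miR-92a-3p lie in exons of MIR17HG on chromosome 13 (91351314 to 91351391) and of a noncoding transcript on chromosome X (134169538 to 134169612). MIR22 lies in an exon of MIR22HG on chromosome 17 from 1713903 to 1713987. MIR10A overlaps an exon of HOXB4 on chromosome 17 (48579838 to 48579947), and MIR10B lies in an intron of HOXD3 on chromosome 2 (176150303 to 176150412).

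At 10 RPM or more in both libraries, 335 miRNAs were counted as expressed, with 161 at 100 RPM, 61 at 1000 RPM and 18 at 10000 RPM or more. The pool was concentrated: 9 miRNAs in replicate 1 and 8 in replicate 2 held 50% of the RPM, and 44 in each held 90%. A level of 10 RPM corresponded to 108 and 154 reads. Another 145 miRNAs were listed above 0 in replicate 1 alone and 196 in replicate 2 alone, none above 0.519 RPM.

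The 19 family lists held 65.5% ± 0.644 of the RPM, with 68 of their 76 members at 10 RPM or more in both libraries. Of these, 18 group miRNAs by the seed, the part that pairs with targets, and held 57.3% ± 1.06, with 63 of 71 members at that level. The other, the miR-23/24/27 group, joins miRNAs of different seeds that lie in shared genomic clusters. The miR-99/100 family held the most, 11.2% ± 2.67, nearly all of it miR-100-5p and miR-99b-5p, while miR-99a-5p stood at 41.1 ± 7.25 RPM. The miR-25/92 family held 9.68% ± 0.0445, led by miR-92a-3p and miR-92b-3p. The let-7 family, known as repressors of growth genes, held 9.28% ± 0.483 with all 9 members expressed, led by let-7a-5p and let-7f-5p. The ranges of mean ± SD of these 3 families overlapped, and their order was not resolved. With copies summed, the let-7 family stood first at 16.9%, ahead of the miR-25/92 family at 12.0% and the miR-99/100 family at 8.70%. These sums appear to count many reads more than once.

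The miR-23/24/27 group held 8.27% ± 0.418 (miR-27b-3p and miR-27a-3p highest), the miR-30 family 6.46% ± 1.26 (miR-30a-5p and miR-30d-5p), the miR-10 family 5.69% ± 0.349 (miR-10a-5p and miR-10b-5p) and the miR-181 family 4.48% ± 0.962, where miR-181b-5p at 6196 ± 1689 RPM followed miR-181a-5p. With copies summed, which appears to count many reads more than once, the miR-181 family held 6.89%. The miR-221 and miR-222 family held 2.27% ± 0.123, with miR-222-3p at 9244 ± 187 RPM and miR-221-3p at 8458 ± 658 RPM. The miR-15/16 family held 1.75% ± 0.351, with miR-15b-5p at 484 ± 84.1 RPM below miR-16-5p, and the miR-26 family 1.72% ± 0.167, with miR-26b-5p at 1212 ± 45.6 RPM. In the miR-125 family (1.40% ± 0.191) miR-125a-5p stood at 6374 ± 669 RPM and miR-125b-5p at 4551 ± 887 RPM. The miR-148 and miR-152 family held 1.10% ± 0.223, with miR-148a-3p at 6153 ± 1425 RPM and miR-148b-3p at 2248 ± 335 RPM.

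The other families held less than 1% each. The miR-17 family held 0.759% ± 0.0208, led by miR-93-5p (2040 ± 87.0 RPM) and miR-20a-5p (1823 ± 79.1 RPM), and the miR-103 and miR-107 family 0.639% ± 0.129, with miR-103a-3p at 4357 ± 852 RPM and miR-107 at 619 ± 118 RPM. The miR-130 and miR-301 family held 0.257% ± 0.0149 (miR-301a-3p 624 ± 14.7 RPM, miR-130a-3p 586 ± 30.2 RPM) and the miR-29 family 0.233% ± 0.0277 (miR-29a-3p 1686 ± 235 RPM, miR-29b-3p 105 ± 7.15 RPM). The miR-19 family held 0.158% ± 0.00985 (miR-19b-3p 866 ± 50.3 RPM, miR-19a-3p 363 ± 18.5 RPM) and the miR-320 family 0.150% ± 0.0278 (miR-320a 1092 ± 198 RPM, miR-320b 59.0 ± 8.35 RPM). In the miR-34 and miR-449 family, which includes targets of p53, only miR-34a-5p (510 ± 5.65 RPM) and miR-34c-5p (11.3 ± 3.13 RPM) had a mean above 10 RPM, and the family held 0.0683% ± 0.00174. Of the 13 family lists with at least 3 members in the table, 11 had a median level at or above the 95th percentile of 10000 random lists of the same size, a description of these libraries and not a test. Over all lists with at least 3 members it was 18 of 28, so a high median was common among them.

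Members of one genomic cluster, often made from a shared primary transcript, accumulated at different levels. In the miR-17-92 cluster, an oncogenic cluster, all 6 members were expressed and spanned 284-fold, from miR-92a-3p down to miR-18a-5p at 186 ± 21.5 RPM, with miR-20a-5p the next highest after miR-92a-3p. With copies summed the span was 524-fold, since miR-92a-3p shares its reads with a hairpin on the X chromosome. The span was 138-fold in the miR-183-96-182 cluster, from miR-182-5p (7040 ± 3.20 RPM) through miR-183-5p (532 ± 166 RPM) to miR-96-5p (51.1 ± 9.12 RPM). It was 13.2-fold in the miR-106b-25 cluster, from miR-25-3p (4417 ± 642 RPM) through miR-93-5p to miR-106b-5p (334 ± 11.6 RPM). On the X chromosome, 8 of 13 members of the miR-506-514 cluster were expressed over 25.9-fold, from miR-509-3p (281 ± 24.1 RPM) and miR-508-3p (119 ± 32.5 RPM) to miR-513c-5p (10.9 ± 0.596 RPM). With a minimum of 1 RPM that span was 254-fold.

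Listed members of the other clusters stood low in RPM, but only C19MC had a median that was low among random lists. The medians leave out names without a row, 2 of 21 for C19MC and 5 of 33 for DLK1-DIO3. Such names may lack a row because no read was seen. Both medians may thus be too high, and the contrast between them is not firm. None of the 19 listed members of the placental cluster C19MC reached 10 RPM in both libraries, the highest being miR-516a-5p (1.94 ± 0.650 RPM) and miR-512-3p (1.41 ± 0.0277 RPM), and the median of the list stood at percentile 2.88 of random lists, or at 6.12 without replicate 1 and 4.31 without replicate 2. Of the 28 listed members of the imprinted DLK1-DIO3 cluster at 14q32, 2 were expressed, miR-411-5p (18.3 ± 2.77 RPM) and miR-409-3p (12.1 ± 2.58 RPM), 1.51-fold apart. MiR-381-3p, second in that cluster by mean, stood at 12.8 ± 5.40 RPM and was below 10 RPM in replicate 2. The median of the 14q32 list stood at percentile 31.0 of random lists. Of the 4 miRNAs listed for the miR-106a-363 cluster, a relative of miR-17-92 on the X chromosome, miR-363-3p (12.0 ± 1.92 RPM) was expressed and miR-106a-5p stood at 5.27 ± 0.523 RPM. Their median stood at percentile 76.4, above most random lists. The list left out mir-92a-2 and mir-19b-2, which lie in the same host transcript and were assigned 44452 ± 1034 RPM of miR-92a-3p and 866 ± 50.3 RPM of miR-19b-3p, reads shared with the copies in the miR-17-92 cluster, so the output of the whole X-linked cluster was not resolved.

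Of 10 miRNAs associated with melanocytes or melanoma, 6 were expressed and each of these stood above 1000 RPM. They were miR-21-5p, miR-222-3p, miR-221-3p, miR-182-5p, miR-204-5p (2632 ± 190 RPM) and miR-146a-5p (2039 ± 690 RPM). The remaining 4 were near the limit of counting: miR-155-5p had 1.18 ± 0.293 RPM and miR-137 0.472 ± 0.117 RPM. MiR-211-5p, encoded in an intron of the melanocyte gene TRPM1 (MIR211, chromosome 15, 31065032 to 31065141), had 3 and 2 reads, while miR-204-5p, its relative with the same seed, encoded in an intron of TRPM3 (MIR204, chromosome 9, 70809975 to 70810084), had 29920 and 38534. MiR-214-3p had 2 reads and 1 read.

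Lists for 7 other cell types held a small share of the RPM. Of their 45 names, 32 were in the table, 10 were at 10 RPM or more in both libraries, and together they made up 0.411% ± 0.0258 of the RPM. The median of the mesenchymal list stood at percentile 96.3 of random lists, above the 95th, that of the liver and endothelial list at 91.5 and that of the epithelial list at 86.9. The neuronal list was led by miR-9-5p (1018 ± 91.0 RPM) and miR-218-5p (42.9 ± 2.22 RPM). The mesenchymal list was led by miR-199a-3p (843 ± 14.1 RPM) and miR-199b-5p (707 ± 61.6 RPM), while miR-199a-5p stood at 2.61 ± 1.08 RPM. The endothelial miR-126-5p stood at 200 ± 55.4 RPM and miR-126-3p at 25.4 ± 0.813 RPM, and the liver miRNA miR-122-5p had 3 and 8 reads. The red cell miRNA miR-486-5p stood at 186 ± 20.7 RPM, miR-142-5p followed in the blood list at 2.21 ± 0.0106 RPM, and miR-451a, another red cell miRNA, had 1 read in replicate 1 and 0 in replicate 2, where a count of 0 allows up to 0.194 RPM. The epithelial list reached 28.8 ± 3.66 RPM for miR-200b-3p and 19.4 ± 5.36 RPM for miR-141-3p. The muscle list (miR-499a-5p 1.09 ± 0.162 RPM, miR-133a-3p 0.388 ± 0.366 RPM) and the pluripotent list (miR-373-3p 0.694 ± 0.0647 RPM, miR-372-3p 0.171 ± 0.150 RPM) had no member at 10 RPM. Entries that overlap tRNA, snRNA or snoRNA sequences, listed as a check of RNA quality, made up 0.0521% ± 9.71e-05 with a median at percentile 96.7. They were led by miR-1260b (179 ± 33.2 RPM) and miR-3607-3p (142 and 41.4 RPM). The small SD of the sum hides opposite shifts: miR-3607-3p was higher in replicate 1 and miR-4454 (39.4 and 95.5 RPM) in replicate 2. RNA breakdown itself was not tested.

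**Figure D2:**
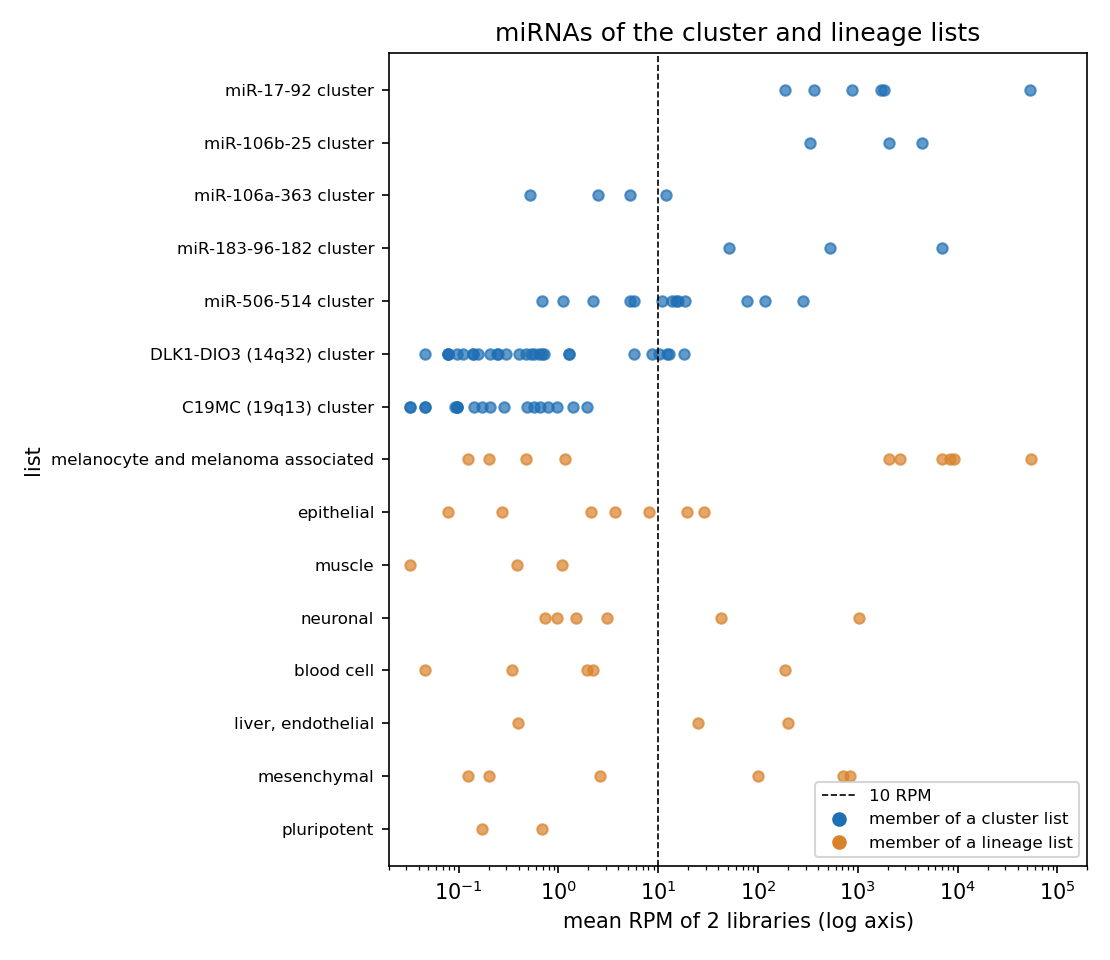
Mean RPM over 2 libraries (log axis) of each miRNA found in the table, by cluster list (blue) and lineage list (orange), with a dashed line at 10 RPM. No C19MC member lies right of the line, and the melanocyte and melanoma list splits into 6 miRNAs above 1000 RPM and 4 near or below 1 RPM.

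The hairpin arms showed strong preferences. Of 134 hairpins with both arms listed and a summed level of 100 RPM or more, 77 had the 5p arm over 2-fold higher in both libraries, 47 the 3p arm, and 10 neither. The median ratio between arms was 45.4-fold, and the sign of the ratio differed between the libraries in 3 hairpins. Among hairpins with 1000 RPM or more, the most balanced were mir-151a (log2 5p over 3p -0.22 ± 0.05; miR-151a-5p 4839 ± 412 RPM, miR-151a-3p 5632 ± 660 RPM), mir-199b (-0.24 ± 0.15; miR-199b-5p against miR-199b-3p at 833 ± 12.6 RPM, a 3p arm whose reads cannot be told from those of mir-199a) and mir-423 (-1.19 ± 0.12; miR-423-5p 1767 ± 317 RPM, miR-423-3p 4065 ± 1067 RPM). The most one-sided with a pseudocount of 1 RPM were mir-26a-1 (11.83 ± 0.02), mir-186 (11.42 ± 0.78) and mir-182 (11.35 ± 0.11), all toward the 5p arm, with 3p arms of 2.35 ± 0.441, 2.77 ± 1.71 and 1.70 ± 0.207 RPM. Their order depends on the pseudocount: without it mir-192 came first, with a 5p arm of 4603 ± 159 RPM and a 3p arm of 0.884 ± 0.0579 RPM. Of the 134 hairpins, 34 had an arm shared with another hairpin, such as mir-26a-1, mir-16-1, mir-24-1, mir-199a-1 and mir-199b, so the arm ratio of the single hairpin was not resolved. In the other 100, 55 favoured the 5p arm, 36 the 3p arm and 9 neither, with a median ratio of 28.5-fold.

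The libraries were then compared with each other, as the only measure of error. Across 357 miRNAs at 10 RPM or more in at least 1 library, Pearson's r of log2(RPM + 1) was 0.993 (95% bootstrap interval 0.991 to 0.994) and Spearman's rho 0.987 (0.982 to 0.990). These are correlations across miRNAs, which are not independent replicates. Across 346 miRNAs with a mean of 10 RPM or more, the median absolute log2 difference was 0.25, or 1.19-fold, and 6 differed by over 2-fold, of which 5 were higher in replicate 1. The 6 included miR-3607-3p, higher in replicate 1, and miR-4454, the only one higher in replicate 2. Both are among the entries that overlap tRNA, snRNA or snoRNA. The median difference hardly moved with abundance, from 0.28 at 10 to 100 RPM to 0.25 at 10000 RPM or more, where counting error alone gives 0.073 and 0.0027. The 2 columns were thus not a single library deposited again. No spread between preparations of one RNA was measured, so technical and biological spread were not told apart.

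MiR-193a-3p stood at 149 RPM in replicate 1 and 65.1 RPM in replicate 2, 2.28-fold apart, and miR-455-3p at 144 and 69.4 RPM, 2.07-fold apart. Their adjusted p in a two-sided Fisher's exact test on reads were 8.1e-96 and 3.8e-75. They were the only miRNAs at a mean of 100 RPM or more among the 40 of 869 tested that passed an adjusted p of 0.05 and differed by over 2-fold, 29 of them higher in replicate 1 and 11 in replicate 2. The median ratio of expressed miRNAs was -0.10 on the log2 scale, and after scaling by it 38 passed, 23 higher in replicate 1 and 15 in replicate 2, a share of 60.5% in place of 72.5%. This test compares 2 libraries by counting error and not conditions. MIR193A lies on chromosome 17 from 31559996 to 31560083 and MIR455 on chromosome 9 from 114209434 to 114209529, in an intron of COL27A1.

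**Figure D3:**
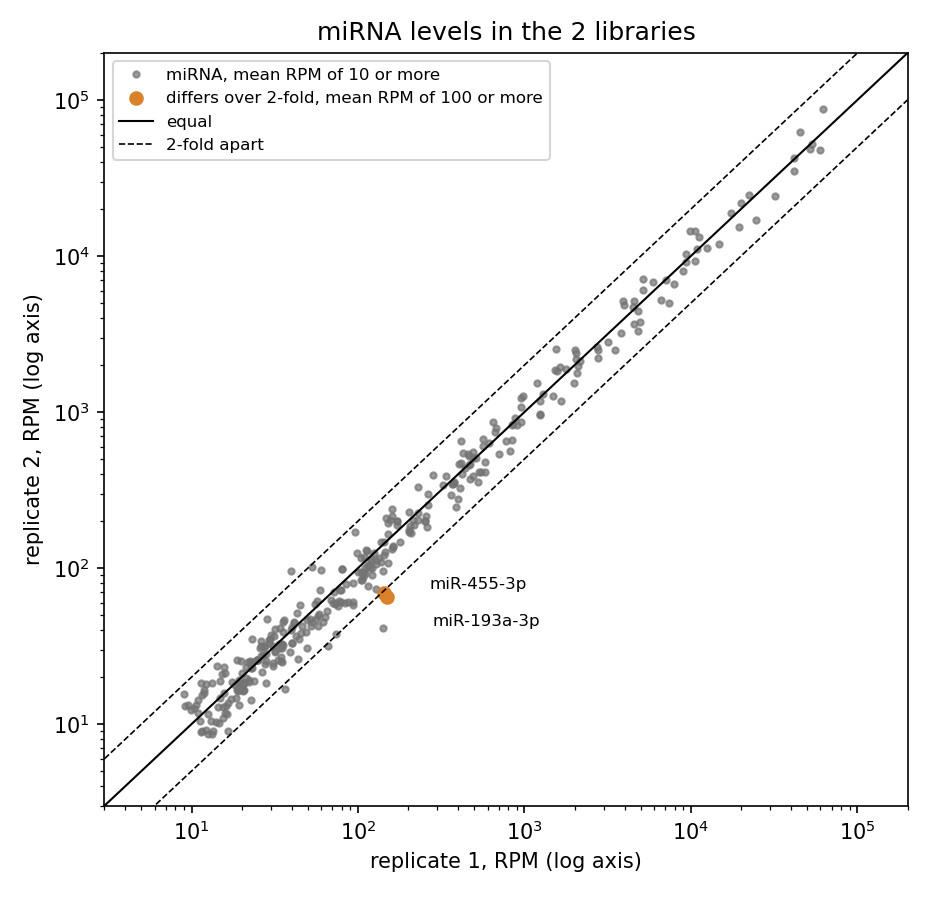
RPM of each miRNA with a mean of 10 RPM or more in replicate 1 (x) and replicate 2 (y), both on log axes, with lines for equal values and for 2-fold differences. MiR-193a-3p and miR-455-3p (orange) are 2.28-fold and 2.07-fold higher in replicate 1.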

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

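Summed copies, shares of the deposited total, unshared arms, arm ratios without a pseudocount, family lists without the miR-23/24/27 group, other neighbour distances and subsets of neighbours or copies were tests chosen only after the result was seen. The other alternatives in this paragraph were planned. Summing copies changed first place from miR-100-5p to let-7a-5p and, among families, from miR-99/100 to let-7. Such sums appear to count many reads more than once. Without a pseudocount the most one-sided hairpin changed from mir-26a-1 to mir-192. In each alternative to the library test, more of the called miRNAs were higher in replicate 1. The number of expressed miRNAs was 593 at a minimum of 1 RPM and 161 at 100 RPM. The share of the top 10 was 54.5% without miR-100-5p, 60.1% with copies summed and 43.8% of the deposited total, and the share of the 19 family lists was 61.9%, 72.4% and 51.1% in the same order; these follow from what the alternatives leave out or add. Over all listed miRNAs Pearson's r was 0.995 and Spearman's rho 0.906. A pseudocount of 10 gave a median absolute log2 difference of 0.21 and 3 miRNAs over 2-fold apart, and a minimum of 100 RPM gave 2. With no fold minimum, 300 miRNAs differed between the libraries, including the 40 of the stricter test. At a summed level of 10 RPM, 104 hairpins favoured the 5p arm, 79 the 3p arm and 25 neither, and at a 4-fold limit 70, 39 and 25, so the 5p arm led in each. The span of the miR-17-92 cluster was 524-fold with copies summed. At a minimum of 1 RPM the span was 254-fold in the miR-506-514 cluster and 3.20-fold at 14q32. At the minimum of 10 RPM, leaving out either replicate gave 1.58 to 1.99 at 14q32. The cause was not tested where the alternative does not itself admit more or fewer miRNAs. The medians of single lists stayed on their side of the 95th percentile in 167 alternatives, but the percentiles themselves moved, as for the muscle list from 40.5 to 16.8 without replicate 1 and 52.4 without replicate 2. Many of the 167 could hardly have moved. Random lists drawn only from entries above 0 were the same lists, since no row was 0 in both libraries. A pseudocount keeps the order of miRNAs. The count is therefore no measure of how firm the percentiles are. With 2 libraries, leaving 1 out cannot move a share by 1 SD. Family shares moved by more than 1 SD in 15 cases with copies summed (7 higher, 8 lower), 18 as shares of the deposited total (all lower) and 11 without miR-100-5p (10 higher, 1 lower: the miR-99/100 family, 1.74%). The level of the miR-320 family passed the 95th percentile of random lists only with copies summed (95.6). The planned search for BRAF 3' UTR seed sites and its alternatives were not run. No paired analysis was possible because there is 1 group. Depth limits miRNAs near 1 RPM, where 1 read is 0.0924 or 0.0648 RPM.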

Other observations

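The tests of miR-199 and of depth at 10 RPM or more, the analyses of neighbours within 50 kb, without large clusters or among expressed hairpins, and those of clear copy differences, unshared arms and the calls lost by thinning were tests chosen only after the result was seen. So were the rule that an interval must exclude a bound and the removal of 2 pairs of copies. Together they changed the reading of 4 tests from that first obtained. Hairpin level and hairpin GC content had been open, a shift shared by neighbours had been set aside, and the test of copies had been met.

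Mature miRNAs made from several genomic copies often had unequal passenger arms, the arm that differs between copies. Of 11 pairs of copies with a passenger arm at 1 RPM or more, 8 differed by over 5-fold. For miR-125b-5p, miR-125b-1-3p stood at 1368 ± 246 RPM (n = 2) and miR-125b-2-3p at 149 ± 18.6 RPM. For miR-16-5p, miR-16-2-3p stood at 226 ± 36.7 RPM and miR-16-1-3p at 4.65 ± 0.348 RPM, and for miR-24-3p, miR-24-2-5p at 209 ± 7.29 RPM and miR-24-1-5p at 4.94 ± 0.444 RPM. For miR-7-5p, miR-7-1-3p stood at 31.1 ± 2.94 RPM and miR-7-2-3p at 0.518 ± 0.183 RPM. For miR-29b-3p, miR-29b-1-5p stood at 18.0 ± 1.46 RPM and miR-29b-2-5p at 0.893 ± 0.437 RPM.

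A hypothesis is that one copy may supply most of the reads of such a miRNA. If so, the copy with the higher passenger arm should also have the more abundant neighbour within 60 kb, among miRNAs not shared between hairpins. This held in 6 of 7 testable pairs (share 0.857, one-sided exact binomial p = 0.0625). It did not hold for miR-24-3p, where mir-24-2 had the higher passenger arm and the neighbour of mir-24-1, miR-27b-3p, was the more abundant. Among 5 pairs whose differences exceeded the summed SDs, both measures pointed to one copy in 4 (exact p = 0.188). The first count had been 8 of 9 before a tied pair and a repeated pair were removed, and 7 pairs are too few to decide.

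The pair miR-199a-3p and miR-199a-5p gives a like case. MiR-199b-5p was 271 times as abundant as miR-199a-5p, and miR-214-3p, encoded beside one mir-199a hairpin, had 2 reads and 1 read. The reads of the 3p arm, shared by the mir-199a and mir-199b hairpins, may therefore come mainly from mir-199b. The ratio assumes that both 5p arms are equally stable, which was not tested.

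Neighbouring hairpins on the same strand within 10 kb had like levels of their unshared miRNAs. Each hairpin entered at its highest mature name that no other hairpin in the table shares. Where the main arm is shared, the level is thus that of the passenger arm. For example, mir-92a-1 entered as miR-92a-1-5p (69.8 ± 12.6 RPM) and not as miR-92a-3p (52790 ± 972 RPM). The median absolute log2 difference of 169 pairs was 1.16 (95% interval 0.79 to 1.76), against 2.81 for random pairings (permutation p = 0.0001, the smallest these permutations can give). A hairpin inside a cluster can enter a pair on each side, so pairs are not independent. The intervals and permutation p of all neighbour tests may therefore understate the error. It was 1.14 within 50 kb (208 pairs) and 2.28 against 4.13 without the C19MC, 14q32 and miR-506-514 regions (96 pairs, permutation p = 0.0002). Among 43 pairs of hairpins at 10 RPM or more it was 2.64 against 3.18 (permutation p = 0.158). A shared primary transcript is a candidate explanation for the like levels over all listed neighbours, but the likeness was not shown among expressed neighbours. Whether neighbours are present or absent together was not counted, and shared chromatin was not tested.

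Between the libraries, 300 miRNAs had an adjusted p under 0.05 in Fisher's exact test, a number that depth favours, since miR-140-3p passed at a log2 difference of 0.02. A change of whole hairpins as the full cause was set aside. The log2 ratios of the arms of 34 hairpins had r = 0.0578 (across hairpins, not independent replicates). The 95% interval was -0.288 to 0.329, below the 0.5 written for it, and -0.394 to 0.289 for 27 hairpins with unshared arms. GC content of the whole hairpin was set aside likewise (rho = -0.0265 across 171 miRNAs, interval -0.182 to 0.130, against 0.3). Hairpin GC is the same for both arms, so this cannot decide on GC of the sequenced arm, which was not tested. Thinning replicate 2 to the depth of replicate 1 left 270 at that adjusted p and kept 24 of the 40 over 2-fold apart (share 0.6). Of the other 16, 15 no longer passed the adjusted p and 1 fell below the read minimum. All were still over 2-fold apart (median absolute log2 1.76 before and 1.37 after). Lost power alone can give this, so the test could not decide on depth for the low ones. The 6 with a mean of 10 RPM or more all stayed (share 1). Thinning keeps the expected fold and leaves such miRNAs many reads, so this outcome was nearly fixed in advance and decides nothing on depth. A shift shared by neighbouring hairpins was not shown. The median difference of log2 ratios, taken for the same unshared miRNAs, was 0.28 over 43 pairs, against 0.32 for random pairings (permutation p = 0.255). Such a shift stays open only because the interval of that median (0.15 to 0.36) includes 0.23, the 5th percentile of random pairings. No treatment or other condition could be tested as an explanation, as the design gives 1 group.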
